A study of Saccharomyces cerevisiae and Schizosaccharomyces pombe with 42 samples.

How the data were processed

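The data are 5' ends of RNA with a 5' phosphate (5PSeq) from Saccharomyces cerevisiae and Schizosaccharomyces pombe. A fragmented control, in which RNA was broken chemically and its ends phosphorylated before the same library steps, gives the bias of the method and the level of poly(A) RNA. Per the labels, libraries in a group are biological duplicates. Poly(A) RNA was selected except in the ribosomal-RNA-depleted libraries. YPD, H2O2, CHX, SD, XRN1 deletion, fraction and fragmented S. cerevisiae libraries were paired-end, and the iced CHX, SD-His, 3-AT and the S. pombe CHX libraries of the same deposit were read at 1 end. Stationary phase, RNY1 deletion, depleted and 30 min S. pombe libraries belong to a later deposit batch whose labels give no read type.

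Per the labels, the authors used CASAVA 1.8.2 and Novoalign (version not given), with genome builds R64, sacCer3 and ASM294v2, whose roles are not stated. The deposited values used are counts, the whole number of 5' ends at each position and strand in each library, with no scaling. Columns scaled to library totals stood beside them and were not used. The adapter carries random bases, and the labels do not say whether copies of 1 molecule were collapsed. In all 44 columns were read, 2 of them S. pombe spike-in ends pooled over several S. cerevisiae samples.

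Counts were summed on the sense strand over coding sequences of 5920 S. cerevisiae genes (build R64) and 5088 S. pombe genes. The share of S. cerevisiae ends in coding sequences ran from 51.5% to 89.6%, and the S. cerevisiae libraries hold 20995552 ends in sum. With n = 2 the scatter between replicates, as chi-square per degree of freedom, ran from 1.34 to 18.7, the latter for depleted YPD, so counting error alone does not describe it. Frame shares used genes with at least 50 ends, without the first and last 50 nt, and with a position capped at 5.0% of its gene. Position densities are ends over the gene mean, capped at the 99th percentile of sites and averaged over genes with at least 50 ends. Pause scores use the end 17 nt before a codon (A site), genes with at least 0.5 ends per codon, and sites capped at 20 times the gene mean, for 61 sense codons. Ends within 60 nt of a coding sequence were counted as flanking.

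Gene counts were tested by edgeR 4.0.16 (quasi-likelihood, TMM scaling, filterByExpr) in a single fit of all S. cerevisiae groups, with 5368 genes tested, 17 residual degrees of freedom and a common biological coefficient of variation of 0.166. Positions and codons, as log2 values with 0.05 added to densities, were tested by limma 3.58.1 in the same design. Adjusted p values are Benjamini-Hochberg values, two-sided, and 0.05 was the threshold. The 3-AT and polysome groups have 1 library, which is assumed to vary as the other groups do. Frame shares were compared by an exact two-sided permutation test. Interactions tested whether an H2O2 change differed between 5PSeq and fragmented RNA, between the RNY1 deletion and wild type, and with and without CHX on ice; the last was chosen after the data were seen and crosses read types, though each part lies within 1 read type.

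The 16 gene lists were cytosolic and mitochondrial ribosomal proteins, ribosome biogenesis, oxidative stress defence, heat shock and general stress, amino acid biosynthesis, sulfur and methionine, glycolysis and fermentation, respiration and the citric acid cycle, gluconeogenesis with glyoxylate and fatty acid use, stationary phase, proteasome, translation factors, mRNA decay, thiamine and vitamins, and histones. They were tested by camera (limma) with a preset correlation of 0.01 and with an estimated one, and mating type and strain markers are given as counts. Comparisons, tests, lists and most alternatives were fixed before the data were examined. Named genes in the H2O2, XRN1, stationary phase and 3-AT comparisons are deleted genes, the 10 largest rises and falls past the threshold with a mean of at least 100 counts, a standard name and fully separated libraries, and the 2 members with the largest called change of each list that moved. Other comparisons name the 3 largest rises and falls. A gene that this rule picks in the 3-AT comparison is not reported here. Codons CCG, CGA, CAC and CAT are always given. Folds against a group with no count use a floor of 3 counts over the group, and with 1 to 3 counts a ratio with a 95% counting interval is given.

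Alternatives were DESeq2 1.42.0, no scaling, no filter, trimmed coding sequences, removal of the highest position of each gene, fits of only the groups compared, a replicate block, other caps, minimums, offsets, weights and denominators, and each library left out in turn. On data simulated from the H2O2 design, edgeR recovered 52.2%, 97.0% and 100% of genes changed by log2 1, 2 and 3 (5 wrong calls). In the 3-AT design it was 20.9%, 79.1% and 98.5% (3). Recovery was not split by count and may fall at few counts. limma recovered 100% of codon changes of log2 1 and 85% of position changes of 2. Monosome libraries have few ends, so their codon scores were not compared. Python 3.11.15 (numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9) and R 4.3.3 were used.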

Results

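The 5' ends of RNA carrying a 5' phosphate (5PSeq) were mapped at single-nucleotide resolution in budding yeast, Saccharomyces cerevisiae, and in fission yeast, Schizosaccharomyces pombe. An RNA with a 5' phosphate has lost its cap and is being degraded, and 5PSeq counts reads of such ends. Of 42 libraries, 36 came from S. cerevisiae in 19 groups and 6 from S. pombe in 3 groups. The S. cerevisiae groups of 2 libraries each were rich medium (YPD), YPD with 0.2 mM hydrogen peroxide (H2O2) for 5 min, the translation inhibitor cycloheximide (CHX) at 0.1 mg/mL for 5 min, synthetic medium (SD), stationary phase, and synthetic medium without histidine (SD-His). Further groups of 2 were deletions of XRN1 and of RNY1, the latter with and without H2O2, a course of 0, 5 and 30 min of H2O2 with CHX added on ice, ribosomal-RNA-depleted libraries with and without CHX, and monosome fractions. The polysome fraction and 100 mM 3-aminotriazole (3-AT), an inhibitor of histidine synthesis, had 1 library each. Libraries of randomly fragmented RNA, 2 from YPD and 2 from H2O2, served as the background measured in the same way.

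S. cerevisiae libraries held between 13688 and 3095302 mapped ends, with a median of 402616, and S. pombe libraries between 115672 and 7241130. The range was 369323 to 582335 for YPD, 435908 to 657660 for H2O2, 1889706 to 2113646 for the XRN1 deletion, 573801 to 690764 for stationary phase, 148699 to 254086 for SD-His and 168474 for 3-AT. It was 477475 to 686037 for CHX, 141062 to 287551 for SD, 506378 to 562836 for the RNY1 deletion and 468985 to 663169 for that deletion with H2O2. On ice with CHX it was 169918 to 273317 at 0 min, 220381 to 316399 at 5 min and 231485 to 240412 at 30 min. Ribosomal-RNA-depleted libraries held 982671 to 1367135 ends without and 1054545 to 3095302 with CHX. The polysome library held 326224, the monosome libraries 13688 and 18687, and the fragmented libraries 208897 to 485968 in YPD and 146103 to 166525 in H2O2. Intervals and floors given here cover counting error only.

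Ribosomes move in steps of 3 nt, and the first comparison asks whether 5' phosphate ends follow that step. In the 32 5PSeq libraries of S. cerevisiae, 44.9% ± 5.47 (SD) of ends within coding sequences lay at the second base of a codon (frame 1), against 33.04% ± 0.423 in the 4 fragmented libraries. The difference was 11.9 points (exact two-sided permutation p = 1.70e-05 over 58905 splits, conditions taken as exchangeable). The lowest 5PSeq share, 34.1%, exceeded the highest fragmented one, 33.5%. In YPD and H2O2 alone the difference was 8.84 points, 41.9% ± 1.91 against 33.04%, n = 4 each (permutation test, unpaired, p = 0.0286 over 70 splits). The frame 1 share was 40.4% ± 1.21 in YPD, 43.4% ± 0.370 with H2O2, 49.4% ± 0.566 with CHX, 39.9% ± 1.41 in SD, 46.9% ± 2.31 in stationary phase and 41.5% ± 1.09 in SD-His (SD, n = 2 each). It was 45.2% ± 0.259 in the RNY1 deletion, 45.3% ± 0.7505 in that deletion with H2O2, and 49.5% ± 0.141, 46.9% ± 0.312 and 50.8% ± 2.61 at 0, 5 and 30 min with CHX on ice. In the deletion of XRN1, the main cytoplasmic 5' to 3' exonuclease, frame 1 held 34.2% ± 0.0894 and frame 2 held 35.1% ± 0.242. With ribosomal RNA depleted the share was 38.5% ± 1.67 without and 47.0% ± 0.101 with CHX. Single libraries gave 45.5% for 3-AT (95% Wilson interval 45.1 to 45.9) and 41.8% for polysomes (41.5 to 42.0), while the monosome share of 56.4% ± 4.64 rests on 4 to 10 genes. With 2 libraries against 2 no exact test can reach 0.05, so these are values.

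In S. pombe the frame 1 share was 52.5% ± 0.482 after 30 min of CHX and 33.1% ± 0.106 in the fragmented libraries of those cultures (SD, n = 2 each). In the other CHX libraries, which were read at 1 end, it was 37.1% ± 0.921. Ends from S. pombe RNA added to S. cerevisiae samples as a spike-in, pooled over samples, gave 35.3% (95% Wilson interval 35.2 to 35.4) in 5PSeq and 32.4% (32.3 to 32.6) in fragmented libraries. Density at -14 from the start codon was 2.57 after 30 min of CHX and 0.4499 in the fragmented libraries. S. pombe groups were not tested against each other.

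**Figure D1:**
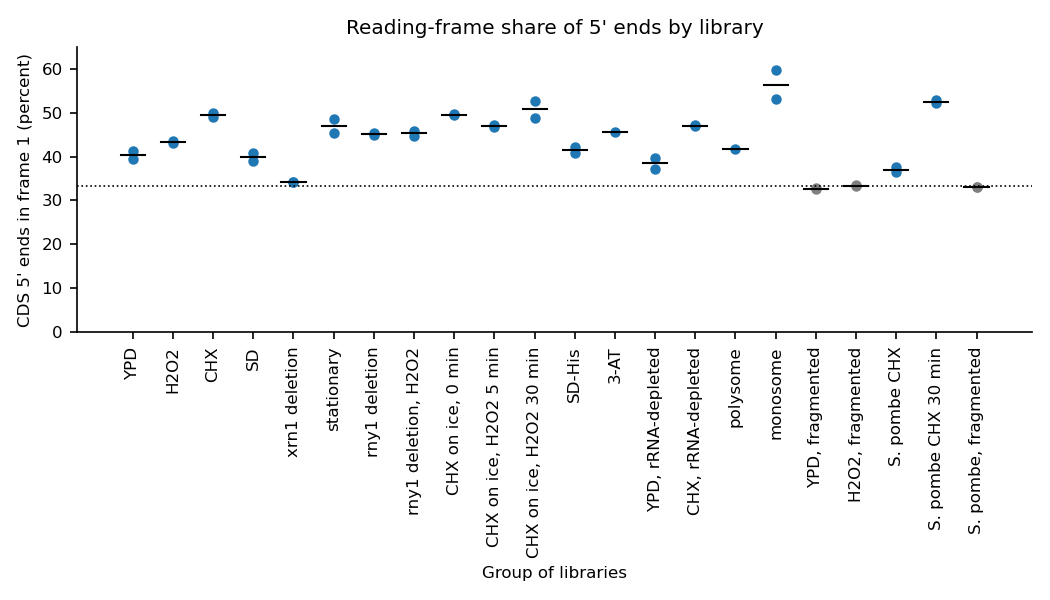
Share of coding-sequence ends in frame 1 (percent, vertical axis) for each group of S. cerevisiae and S. pombe libraries; points are libraries, lines are group means and the dotted line marks an even share between the 3 frames.

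Translation inhibitors change where ribosomes stand on an mRNA, and with CHX the ends at start and stop codons moved. Positions are counted from the first base of the start or stop codon. At -14 from the start codon, where the protected edge of a ribosome at the start codon lies, density rose with CHX from 0.514 ± 0.0134 to 8.25 ± 1.49 times the gene mean (SD, n = 2 each; log2 change 3.87, adjusted p = 2.70e-08). At -17 from the stop codon, the edge of a ribosome at the stop codon, density fell with CHX from 7.74 ± 0.520 to 1.55 ± 0.0290 (log2 change -2.29, adjusted p = 2.95e-07). In ribosomal-RNA-depleted libraries CHX moved both positions likewise, the start by 2.42 (adjusted p = 1.69e-05) and the stop by -1.63 (adjusted p = 5.78e-05) on the log2 scale. The stop position held 10.2 ± 0.255 times the gene mean in stationary phase, a log2 change of 0.39 from YPD that did not pass (adjusted p = 0.598). At -47, 1 ribosome length further from the stop codon, the stationary density was 3.78 ± 0.0950 against 2.08 ± 0.214 in YPD (adjusted p = 0.801). 5PSeq density at -17 exceeded that of fragmented RNA by 1.48 in YPD (adjusted p = 3.86e-04) and by 1.91 in H2O2 (adjusted p = 2.20e-05) on the log2 scale. Among genes with at least 200 ends the YPD difference was 1.18 and did not pass.

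**Figure D2:**
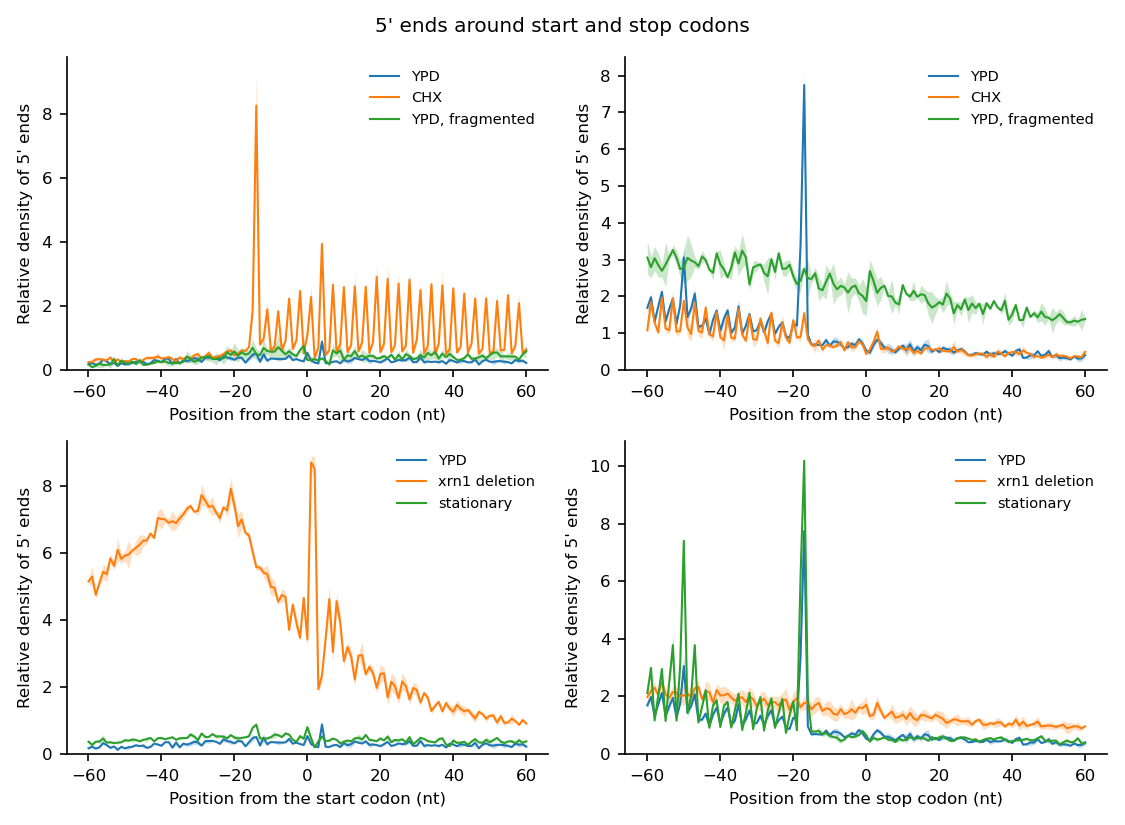
Mean density of 5' ends, as multiples of each gene's mean, against the distance in nt from the start codon and from the stop codon; lines are group means and bands span the libraries of a group.

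H2O2 for 5 min in YPD, the first of the main gene comparisons, changed 5 genes and 8 codons in the fit of all groups. RPS28B, which encodes a protein of the small ribosomal subunit, rose from 236 ± 12.9 to 1001 ± 3.09 CPM, counts scaled to library size (log2 change 2.08, SE 0.264, SD of n = 2 libraries in each group, adjusted p = 1.88e-06). RPS28B (YLR264W) lies on chromosome XII at 673131 to 673334. The ribosomal protein gene RPL43B (log2 change 1.32, adjusted p = 0.0200) and QCR7, a subunit of respiratory complex III (1.39, adjusted p = 0.0483), also rose. Aspartate codons rose, GAT from 0.998 ± 0.0506 to 2.10 ± 0.283 (log2 change 1.07, adjusted p = 3.09e-08) and GAC from 1.04 ± 0.0165 to 1.94 ± 0.202 (0.90, adjusted p = 3.69e-09), as pause scores with the codon in the A site of the ribosome. Of the serine codons, TCC rose by 0.76 (adjusted p = 7.05e-04) and TCT by 0.76 (adjusted p = 0.00388). The codons TGT, TTG, ATC and AGA fell, by log2 changes of -0.32, -0.24, -0.22 and -0.20, calls that ended in a fit of only the groups compared (group-only fit) and without H2O2 replicate 2 or either YPD library. CGA, an arginine codon read slowly, was at 1.55 ± 0.291 in YPD and 0.882 ± 0.132 with H2O2 (-0.81, adjusted p = 0.0599), and the proline codon CCG and the histidine codons CAC and CAT did not pass (adjusted p = 0.795, 0.848 and 0.663).

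Of 5368 genes tested, edgeR called 4 higher and 1 lower with H2O2, and 417 had an unadjusted p under 0.05; the group-only fit called 45 and 12. The other calls, TPM2, a tropomyosin (1.57, adjusted p = 0.00105), and MIG2, a glucose repressor (-1.30, adjusted p = 0.0280), were named after seeing their values. Cytosolic ribosomal protein genes had 2 of 134 members called higher, 7 adjusted over the list alone, with a camera adjusted p = 2.75e-18, lost at adjusted p = 0.442 with an estimated correlation. The lists of respiration (1 of 47 higher, 1 adjusted over the list alone), heat shock genes and histones also passed upward and ribosome biogenesis downward, with no member called in those last 3. With an estimated correlation their adjusted p = 0.442, 0.556, 0.442 and 0.556. Glycolysis, at adjusted p = 0.0285, had adjusted p = 0.556 with an estimated correlation. The calls of RPL43B, QCR7 and MIG2 ended when any of the 4 libraries was left out, and that of TPM2 in 2 of 4 such fits. The count was 1 higher without H2O2 replicate 1 or YPD replicate 2, 2 higher without H2O2 replicate 2 or YPD replicate 1, and none lower. Without scaling, and in DESeq2, the split was 3 higher and 2 lower.

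**Figure D3:**
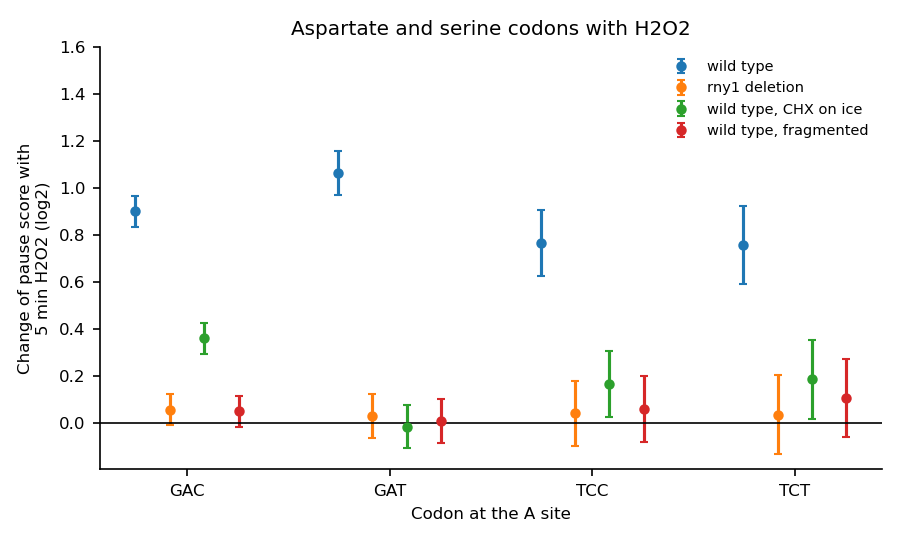
Change of codon pause scores with H2O2 (log2, vertical axis) for aspartate and serine codons in wild type, in the RNY1 deletion, with CHX on ice and in fragmented libraries; points are fitted changes and lines their standard errors.

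In the XRN1 deletion, XRN1 (YGL173C, chromosome VII, 175527 to 180113) had 3 counts, and 854 in wild type. KDX1, a kinase-like gene on chromosome XI, rose from 3 to 467 counts, a ratio of 65.5 (counting interval 22.3 to 319). PCK1, which encodes the gluconeogenic enzyme phosphoenolpyruvate carboxykinase, rose by 5.14, and MIN10, AAD14, BLI1 and PCC1 by 5.23, 4.58, 4.32 and 4.10 on the log2 scale. SPO24, LIN1, ECM9 and TAH1 rose by 3.89, 3.79, 3.66 and 3.65. Lower genes were PHO84, a phosphate transporter (-4.33), the glycolytic gene TDH1 (-3.61), VTC4 of polyphosphate synthesis (-2.95), the iron oxidase FET3 (-2.92), SEC39 (-2.90), AGA1 (-2.80), the drug pump PDR5 (-2.77), and the vacuolar proteases PRC1 (-2.77) and PEP4 (-2.59).

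In all, 1386 genes were higher and 1192 lower in the XRN1 deletion (2928 unadjusted p under 0.05). DESeq2 gave 1538 and 1006, the median of all genes shifted by 0.12. Counts are shares of coding-sequence ends, 51.5% and 51.9% of all ends here and 87.8% and 88.9% in YPD, so a fall is relative. Of 134 cytosolic ribosomal protein genes 79 rose and 3 fell, 82 and 4 adjusted over the list alone, among them RPL14A (3.02) and RPS22B (2.63). That list passed at a camera adjusted p = 4.78e-07, but at adjusted p = 0.631 with an estimated correlation. Mitochondrial ribosomal proteins had 33 of 67 higher and 6 lower (34 and 6 adjusted over the list alone), RSM10 (2.49) and MRPL44 (2.21) among the higher ones, with adjusted p = 0.290 with an estimated correlation. Genes of gluconeogenesis, the glyoxylate cycle and fatty acid use had 12 of 34 higher and 1 lower, 12 and 1 adjusted over the list alone, with FBP1 at least 4.77-fold higher over a floor of 3 counts (adjusted p = 0.114 with an estimated correlation). Glycolysis genes had 1 of 21 higher and 11 lower, PFK1 at -1.90, and heat shock genes 5 of 54 and 25, HSP26 at -3.76. Both kept those counts adjusted over the list alone, and had adjusted p = 0.444 and 0.631 with an estimated correlation. Thiamine and vitamin genes, 8 of 16 higher, did not pass camera (adjusted p = 0.0695). The list medians of amino acid biosynthesis, histones and mRNA decay changed sign between scalings. Lists that did not pass camera were amino acid biosynthesis (15 higher and 15 lower of 62), histones (2 and 3 of 10), mRNA decay (9 and 8 of 36), oxidative stress defence (12 and 7 of 37), proteasome (9 and 5 of 35), respiration (14 and 9 of 47), ribosome biogenesis (28 and 15 of 137), stationary phase (9 and 1 of 28), sulfur genes (7 and 2 of 26) and translation factors (5 and 12 of 38). Genes on chromosome XI stood apart, with a median 1.13 higher on the log2 scale than that of the other chromosomes and 86.3% of 306 genes above it, and KDX1, PCK1, BLI1, PCC1, ECM9 and RPL14A lie there. SIP18, of the heat shock list, was called at an at least 1.963-fold rise and in 1 of 4 fits that leave out a library.

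Ends accumulated upstream of coding sequences in the XRN1 deletion. Of the ends in coding sequences and the 60 nt on either side, the 60 nt before start codons held 23.8% ± 0.759 against 2.14% ± 0.00304 in YPD (SD, n = 2 each). Density at -17 from the start codon rose to 6.62 ± 0.0718 from 0.233 (log2 change 4.57, adjusted p = 5.39e-10) and at -14 to 5.59 ± 0.158 from 0.514 (3.32, adjusted p = 1.22e-08), and at -17 from the stop codon it fell to 1.77 ± 0.343 from 7.74 (-2.11, adjusted p = 1.19e-07). No codon score was called by limma, at 5 unadjusted p under 0.05 of 61 (1 higher in the group-only fit); CCG, CGA, CAC and CAT had adjusted p of 0.764, 0.764, 0.982 and 0.966.

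**Figure D4:**
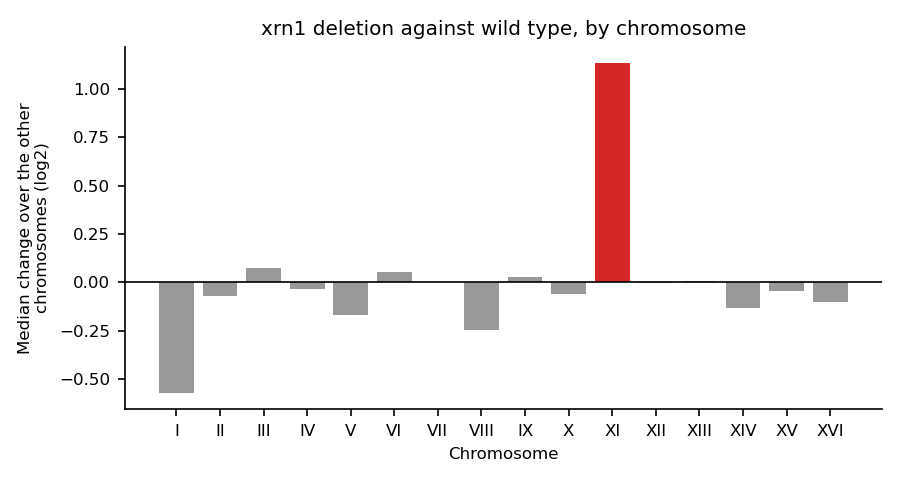
Median log2 change of 5' end counts in the XRN1 deletion over wild type for the genes of each chromosome, relative to the genes of all other chromosomes; bars are medians.

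Stationary phase, compared with growth in YPD, raised genes that use nonfermentable carbon. All 34 genes of gluconeogenesis, the glyoxylate cycle and fatty acid use rose, 34 adjusted over the list alone (camera adjusted p = 1.64e-35, and adjusted p = 2.68e-08 with an estimated correlation). ADH2, the alcohol dehydrogenase that consumes ethanol, was at least 559-fold higher, and the glycerol transporter STL1 at least 97.8-fold. Stationary phase genes rose in 27 of 28 cases, 27 adjusted over the list alone, SPG4 at least 651-fold. Heat shock and stress genes had 43 of 54 higher and 3 lower, 43 and 3 adjusted over the list alone, SIP18, a desiccation-related protein, at least 1323-fold higher and GRE1 9.37 higher on the log2 scale. Respiration and the citric acid cycle had 44 of 47 higher, 45 adjusted over the list alone, with COX5A at 4.07 and SDH2 at 3.97. Translation factors had 1 of 38 higher and 28 lower, 1 and 28 adjusted over the list alone, TEF4 at -3.65 and GCN3 at -2.82.

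Further rises in stationary phase were SPS100 (at least 604-fold), RGI2 (at least 223-fold), the acetate transporter ADY2 (at least 217-fold), the lactate transporter JEN1 (log2 change 9.71), and PIR3 and SPG1, each with 1 count in YPD (ratios of 1857, interval 333 to 7.34e+04, and 839, interval 150.1 to 3.32e+04). The largest falls were the glucose transporter HXT3 (-5.80), INA1 (-5.62), the nucleolar protein NOP56 (-4.46), the proton pump PMA1 (-3.78), RPS9B (-3.56), GAR1 (-3.31), NOP58 (-3.31), GLY1 (-3.19) and ERG4 (-3.17). Cytosolic ribosomal proteins had 124 of 134 lower and none higher, 127 adjusted over the list alone (adjusted p = 0.104 with an estimated correlation), with RPL9A at -3.51. Ribosome biogenesis had 5 of 137 higher and 88 lower, 5 and 88 adjusted over the list alone (adjusted p = 0.213 with an estimated correlation), with RPA43 at -3.47. All 10 histone genes fell, 10 adjusted over the list alone, HTA2 by -2.74 and HHF2 by -2.73 (adjusted p = 0.0556 with an estimated correlation). Glycolysis, 2 of 21 higher and 13 lower (2 and 13 adjusted over the list alone), included HXT1 at -5.28 (adjusted p = 0.247 with an estimated correlation). Amino acid biosynthesis had 13 of 62 higher and 32 lower, 13 and 33 adjusted over the list alone, GDH3 at 6.81 and LEU9 at -2.81 (adjusted p = 0.104 with an estimated correlation). Oxidative stress defence had 19 of 37 higher and 8 lower, 19 and 8 adjusted over the list alone, with CTT1, a catalase, at 5.24 and GPX1 at 4.70 (adjusted p = 0.247 with an estimated correlation). The lists of mitochondrial ribosomal proteins (9 of 67 higher, 8 lower), mRNA decay (6 and 9 of 36), proteasome (4 and 15 of 35), sulfur and methionine (7 and 7 of 26) and vitamins (8 and 2 of 16) did not pass camera, at adjusted p of 0.912, 0.343, 0.0879, 0.338 and 0.338, and the medians of mitochondrial ribosomal proteins, mRNA decay and sulfur change sign with scaling.

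Of 5368 genes, 1513 rose and 1444 fell in stationary phase, 3210 having an unadjusted p under 0.05. Without scaling it was 1204 and 1913 with a median shift of -0.33, and in DESeq2 1875 and 1076 with 0.28. Among codons ACG (0.68), GAA (0.22) and AGA (0.16) rose and TCC (-0.52), ACT (-0.45), TTC (-0.40), GCC (-0.40), ACC (-0.35), GTT (-0.34), TAC (-0.33) and CCA (-0.31) fell, while CGA, CCG, CAC and CAT did not pass (adjusted p = 0.408, 0.2995, 0.130 and 0.274). No codon was called without stationary replicate 1, without YPD replicate 1 or with the 10 codons on either side as denominator, and none was higher in the group-only fit. The stationary libraries come from another deposit batch than YPD. In the RNY1 deletion libraries of that batch 2 gluconeogenesis genes were higher and 3 lower than in YPD, and no stationary phase gene was higher and 5 lower. The rise of these lists was thus not shared by that group of the batch. These deletion libraries also differ from YPD in genotype, so batch and growth state cannot be told apart.

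3-AT against SD-His asks what histidine shortage does, with 1 library against 2. Amino acid biosynthesis rose, with 42 of 62 genes higher, 47 adjusted over the list alone (camera adjusted p = 3.26e-84, and adjusted p = 1.07e-09 with an estimated correlation). ARG7, ARG4, ARG56 and ARG1 of arginine synthesis rose by 4.00, 3.85, 3.56 and 3.44, and LYS1 of lysine synthesis by 4.37. SNZ1, of vitamin B6 synthesis, rose by 6.51, from 58.9 ± 15.1 (SD, n = 2) to 5623 CPM, TMT1 by 4.81, the sulfite pump SSU1 by 4.15 and the 3-AT resistance transporter ATR1 by 3.79. Sulfur and methionine genes had 12 of 26 higher, 16 adjusted over the list alone (adjusted p = 3.94e-07 with an estimated correlation), among them STR3 at 3.71, called in 1 of 2 fits without 1 library. The histidine codons CAT and CAC rose, from 2.42 ± 0.150 to 7.05 (log2 change 1.54, adjusted p = 3.15e-06) and from 1.601 ± 0.0737 to 3.18 (0.99, adjusted p = 1.47e-05).

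Density 17 nt before CAT codons was 11.1 with 3-AT against 3.604 and 2.98 in SD-His, and 47 nt before them, where a following ribosome would end, 5.01 against 1.24 and 1.43. Before CAC codons it was 4.61 against 1.90 and 1.86, and 1.91 against 1.38 and 1.54. CTG, scored in 1 library of each group, had a change of 0.84 and AAA (-0.57) and ATC (-0.30) fell. In the group-only fit CAT alone was called, and with a minimum of 2 ends per codon AAA stood at 1.00. Without SD-His replicate 1 or 2 the count was 5 or 4 codons higher and 6 or 9 lower, against 3 and 2. CCG and CGA did not pass (adjusted p = 0.170 and 0.924). Lower genes were SAH1 (-2.36), PSA1 (-1.88), TEF4 (-1.60), SSC1 (-1.38) and UTH1 (-1.35), besides NOP56 (-1.83), ECM33 (-1.68), CBF5 (-1.31), EFB1 (-1.30) and ACC1 (-1.23), whose calls ended in 1 of 2 fits without 1 SD-His library. Cytosolic ribosomal proteins (1 of 134 higher, 1 lower, and the same adjusted over the list alone) and ribosome biogenesis (5 of 137 lower, 5 adjusted over the list alone) passed downward, each at adjusted p = 0.583 with an estimated correlation. Translation factors, with 1 of 38 lower and 1 adjusted over the list alone, had adjusted p = 0.264 with an estimated correlation. In all 188 genes rose and 59 fell, at 883 unadjusted p under 0.05. Without scaling it was 162 and 89, with a median shift of -0.12, and in the group-only fit 167 fell.

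CHX for 5 min raised SPO24, a small sporulation gene, by 2.94 (adjusted p = 1.42e-08), the transcription coactivator MBF1 by 1.73 and TOS6 by 1.72, the latter in 3 of 4 fits without 1 library. In ribosomal-RNA-depleted libraries CHX raised SPO24 by 3.24, QCR10 of respiratory complex III by 2.78 and the mitochondrial ribosomal protein MRPL31 by 2.65, and lowered KRI1 (-1.59), NOP14 (-1.54) and ESF1 (-1.50) of ribosome biogenesis in 3, 3 and 2 of 4 such fits. Histones (7 of 10 higher, 8 adjusted over the list alone) and mitochondrial ribosomal proteins (23 of 67, and 25 higher and 1 lower adjusted over the list alone) rose there, at adjusted p = 0.0108 and adjusted p = 0.0177 with an estimated correlation. Lists that passed upward and were lost with an estimated correlation were, in the first pair, cytosolic ribosomal proteins (1 of 134, 2 adjusted over the list alone; adjusted p = 0.593), respiration (3 of 47, 5; adjusted p = 0.226), histones (1 of 10, 3; adjusted p = 0.182) and mitochondrial ribosomal proteins (none of 67, 2; adjusted p = 0.217), besides ribosome biogenesis downward (1 of 137 higher, 1; adjusted p = 0.593). In the depleted pair they were cytosolic ribosomal proteins (31 of 134, 39; adjusted p = 0.415), respiration (18 of 47 higher and 2 lower, 20 and 3; adjusted p = 0.122) and, downward, ribosome biogenesis (11 of 137 higher and 28 lower, 14 and 38; adjusted p = 0.641; upward without YPD replicate 1). The counts were 36 higher and 5 lower in the first pair (557 unadjusted p under 0.05) and 457 and 390 in the depleted pair (1643), the latter 609 and 170 without scaling, with a median shift of 0.14. In the group-only fit they were 133 and 28 in the first pair and 21 and 0 in the depleted pair. With coding sequences trimmed by 50 nt at both ends the first pair had 12 and 3, and 9 were lower in DESeq2 or with every counted gene tested. Leaving out any of the 4 libraries of the first pair gave 9 to 14 higher and 0 to 1 lower. In the depleted pair the counts were 157 and 13 without YPD replicate 1, 902 and 926 without YPD replicate 2, 196 and 128 without CHX replicate 1, and 107 lower without CHX replicate 2. CAC fell in the depleted pair (-0.43, adjusted p = 0.0425), a call that ended when any of the 4 libraries was left out. In the first pair limma called no codon, with 6 unadjusted p under 0.05, but 1 higher and 1 lower in the group-only fit and 1 higher without YPD replicate 2.

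SD against YPD raised ADE17 and ADE2, of purine synthesis, by 4.59 and 3.08 and MTD1, of one-carbon metabolism, by 3.57. CHA1, the serine deaminase, fell (-3.34), as did UTP23 (-2.20) and DBP2 (-1.93, in 3 of 4 fits without 1 library) of ribosome biogenesis and RNA metabolism. Heat shock genes rose in 30 of 54 cases, 35 adjusted over the list alone, gluconeogenesis in 7 of 34, 7 adjusted over the list alone, and sulfur genes in 6 of 26, 7 adjusted over the list alone. Those 3 hold with an estimated correlation, at adjusted p = 0.0413, 0.00851 and 0.00619. Ribosome biogenesis had 54 of 137 lower, 81 adjusted over the list alone (adjusted p = 0.0748 with an estimated correlation). Also lost with an estimated correlation were stationary phase genes (7 of 28 higher, 10 adjusted over the list alone, adjusted p = 0.0901), respiration (11 and 1 lower of 47, 15 and 2, adjusted p = 0.119) and amino acid biosynthesis (14 and 3 lower of 62, 15 and 6, adjusted p = 0.213). So were oxidative stress defence (5 and 1 lower of 37, 5 and 1, adjusted p = 0.231), glycolysis (5 of 21, 6 and 1 lower, adjusted p = 0.280), translation factors (2 lower of 38, none, adjusted p = 0.350; upward without SD replicate 2) and cytosolic ribosomal proteins (11 lower of 134, 11, adjusted p = 0.510). The codons CCG (1.30), GGG (1.27), CCC (1.02), TCT (0.50), TCC (0.44) and TCA (0.43) rose and AGG (-1.27), CGT (-1.05), GGA (-0.99), TTA (-0.45) and AAG (-0.21) fell. CCC, AGG and GGA were scored in 1 SD library. In the group-only fit no codon was called, and with a minimum of 2 ends per codon GGG stood at -0.42. The other calls also ended with 1 library left out, CCG without YPD 1 (replicate numbers), GGG without SD 1 or YPD 1, CGT without SD 1 or YPD 2, TTA without SD 1 or either YPD, and TCT, TCC, TCA and AAG without SD 2 or either YPD. In all 296 genes rose and 293 fell, 1374 at an unadjusted p under 0.05, 443 and 216 in DESeq2 with a median shift of 0.12, and 35 and 11 in the group-only fit. The counts were 80 and 83 without SD replicate 2, 162 and 155 without YPD replicate 1, and 174 and 157 without YPD replicate 2.

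In the deletion of RNY1, which encodes a vacuolar RNase T2, RNY1 (YPL123C, chromosome XVI, 317641 to 318945) had no count in the deletion and 48 in wild type, at least 15.5-fold lower. ENP1 and RCM1 of ribosome biogenesis rose by 2.71 and 2.64 and VAN1 of mannosylation by 2.57, while PHO84 (-5.22), FIT3 of iron uptake (-3.73) and the initiation factor SUI1 (-3.24) fell. Cytosolic ribosomal proteins had 6 of 134 higher and 66 lower, 6 and 68 adjusted over the list alone, and ribosome biogenesis 59 of 137 higher and 8 lower, 62 and 8 adjusted over the list alone (each at adjusted p = 0.339 with an estimated correlation). Glycolysis had 15 of 21 lower, 16 adjusted over the list alone (adjusted p = 0.140 with an estimated correlation). Histones (1 of 10 higher and 6 lower, 1 and 6 adjusted over the list alone, adjusted p = 0.140), mitochondrial ribosomal proteins (22 of 67 higher and 5 lower, 24 and 5, adjusted p = 0.339), oxidative stress defence (3 and 14 of 37, 3 and 14, adjusted p = 0.339), respiration (2 and 15 of 47, 2 and 15, adjusted p = 0.339) and heat shock genes (2 and 15 of 54, 2 and 15, adjusted p = 0.484) were lost in the same way, so none of the 8 holds with an estimated correlation. The codons CCG (1.12), CCC (0.47), GAG (0.42), GAA (0.36), CCA (0.31) and AGA (0.25) rose and 19 fell, from TGC (-0.61) to GGT (-0.18). It was 2 higher without either deletion library or YPD replicate 1, 8 and 9 lower without deletion replicate 2 or YPD replicate 1, and 0 and 2 with a minimum of 2 ends per codon. The counts were 1040 higher and 834 lower, 2318 at an unadjusted p under 0.05, and 827 and 1047 without scaling, with a median shift of -0.15. Leaving out 1 library gave 472 to 592 lower genes, moved most by either deletion library. The deletion and wild type come from different deposit batches, so batch and genotype cannot be told apart. The labels give the deletion libraries the backgrounds BY4742, BY4743, BY4744 and BY4745 with mating type a, and wild type BY4741. LYS2, which BY4742 lacks, held 300 counts in the deletion and 300 in YPD, and MET17, which BY4741 lacks, none and 1.

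With H2O2 the RNY1 deletion raised 1 gene, the sulfiredoxin SRX1, from 1 to 70 counts, a ratio of 65.5 (interval 11.4 to 2624), adjusted p = 3.58e-04, in 3 of 4 fits without 1 library, the exception being replicate 1 of the untreated deletion. SRX1 (YKL086W, chromosome XI, 278281 to 278664) was named after its value was seen. The group-only fit called 7 higher and a fit of every counted gene 2. No gene fell by edgeR, at 88 unadjusted p under 0.05, and DESeq2 called none, at 92. Oxidative stress defence passed upward (1 of 37, 1 adjusted over the list alone, adjusted p = 0.273 with an estimated correlation), as did cytosolic ribosomal proteins (none of 134 called, adjusted p = 0.923), and mitochondrial ribosomal proteins downward (none of 67 called, adjusted p = 0.757), and none holds. The codons CCC (-0.77, adjusted p = 0.0173) and CCA (-0.39, adjusted p = 0.0444) fell, calls that ended when any of the 4 libraries was left out, and GAT was at 0.931 ± 0.0138 without and 0.9504 ± 0.00136 with H2O2. The H2O2 change of GAT in the deletion differed from that in wild type by -1.04 (adjusted p = 9.01e-06), of GAC by -0.84 (adjusted p = 2.48e-06) and of TCC by -0.72 (adjusted p = 0.0373), the last ending when any of the 8 libraries was left out, and GAT (-0.97) and TCC with a minimum of 2 ends per codon. In the fit of all groups edgeR called no gene for this difference, at 271 unadjusted p under 0.05, in the group-only fit 8 higher and 13 lower, and DESeq2 called 1 lower.

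With CHX added on ice, 5 min of H2O2 raised antioxidant genes: cytochrome c peroxidase CCP1 by 3.03 and glutathione peroxidase GPX2 by 2.98, together with the iron reductase FRE1 by 2.85. Oxidative stress defence had 19 of 37 higher, 24 adjusted over the list alone (camera adjusted p = 8.51e-52, and adjusted p = 6.79e-07 with an estimated correlation), and amino acid biosynthesis 3 of 62, 6 adjusted over the list alone (adjusted p = 0.0415 with an estimated correlation). Heat shock genes, 5 of 54 higher and 15 adjusted over the list alone, had adjusted p = 0.159 with an estimated correlation, as did glycolysis, with no member called. Translation factors upward (adjusted p = 0.356) and mitochondrial ribosomal proteins (0.260) and ribosome biogenesis (0.549) downward, with no member called, did not hold either. By 30 min the peroxiredoxin TSA2 had risen from 1 to 544 counts, a ratio of 495 (interval 88.4 to 1.96e+04), and the chaperone HSP42 and RTC3 by 5.00 and 4.89. SDA1 (-2.28) and UTP5 (-2.12) of ribosome biogenesis and the histone gene HTA1 (-2.18) fell. At 30 min heat shock (45 of 54, 46 adjusted over the list alone), oxidative stress (29 of 37, 30), proteasome (22 of 35, 31), stationary phase (13 of 28, 14) and sulfur genes (8 of 26, 10) rose, and ribosome biogenesis (121 of 137, 129) and histones (7 of 10, 8) fell, the second count in each pair being adjusted over the list alone. Those 7 hold with an estimated correlation, at adjusted p = 7.67e-04, 2.13e-05, 7.18e-04, 0.00415, 0.00415, 0.00415 and 0.00618 in that order. Cytosolic ribosomal proteins (88 of 134 lower, 109 adjusted over the list alone), translation factors (16 of 38 lower, 20) and respiration (8 of 47 higher, 7) do not, at adjusted p = 0.107, 0.0509 and 0.428. The counts were 59 higher and 6 lower at 5 min (495 unadjusted p under 0.05; 53 and 15 without scaling, 165 and 85 in the group-only fit, 11 lower in DESeq2, 3 with trimmed coding sequences) and 569 and 619 at 30 min (1758; 783 and 478 in DESeq2, median shift 0.18). At 5 min 36 and 35 genes were higher without 0 min replicate 1 or 2, and 1 to 3 lower without 0 min replicate 2 or either 5 min library. At 30 min 332 were higher and 371 lower without 0 min replicate 2, and 392 lower without 30 min replicate 1. At 5 min GAC rose by 0.36 and CGA fell by 1.05, and density at -17 from the stop codon rose from 1.45 ± 0.203 to 3.84 ± 0.0954 (log2 change 1.38, adjusted p = 0.00285). The GAC and CGA calls ended in the group-only fit, GAC also without 0 min replicate 1 and CGA without 5 min replicate 1 or either 0 min library. The stop call ended without replicate 2 of 5 min or 0 min and among genes with at least 200 ends. At 30 min limma called no codon, with 8 unadjusted p under 0.05, but 9 higher and 5 lower with a minimum of 2 ends per codon, 1 to 2 higher without 30 min replicate 2 or either 0 min library, and 1 lower without 30 min replicate 1.

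Fragmented RNA follows the level of mRNA, and asks whether 5' phosphate ends changed beyond it. With H2O2 edgeR called no gene in the fragmented libraries, at 627 unadjusted p under 0.05, while DESeq2 called 43 higher and 15 lower. Without fragmented YPD replicate 1 edgeR called 13 higher and 1 lower. Density at -17 from the stop codon fell (-0.78, adjusted p = 0.0462) and at -14 from the start codon it rose (1.00, adjusted p = 0.0481). Both calls ended in the group-only fit, among genes with at least 200 ends and with ends summed over genes, the stop also when any of the 4 libraries was left out and the start without either H2O2 library or YPD replicate 2. Histones were lower as a list, with none called and 7 of 10 adjusted over the list alone (adjusted p = 0.0384 with an estimated correlation). Cytosolic ribosomal proteins (adjusted p = 0.582), heat shock genes (0.590; 5 higher adjusted over the list alone), mitochondrial ribosomal proteins (0.590) and respiration (0.650), with no member called, were lost with an estimated correlation. In 5PSeq beyond the fragmented change, RPS28B rose by 3.05 (adjusted p = 4.13e-06), the acyl-CoA binding protein gene ACB1 by 2.15, in 2 of 8 fits without 1 library, and RPL43B by 2.02, in 4 of 8. GAT rose by 1.06 (adjusted p = 6.64e-06), GAC by 0.85 (adjusted p = 2.19e-06) and TCC by 0.71 (adjusted p = 0.0377), and CGA, scored in 1 fragmented H2O2 library, fell by 1.54 (adjusted p = 0.0377). With 1 of the 8 libraries left out the TCC call stood only without fragmented H2O2 replicate 1, and CGA ended in the group-only fit and without either H2O2 library, YPD replicate 1 or fragmented YPD replicate 2. Histones rose as a list, with none called and 8 of 10 adjusted over the list alone (adjusted p = 0.0206 with an estimated correlation), and cytosolic ribosomal proteins had 3 of 134 higher, 46 adjusted over the list alone (adjusted p = 0.165 with an estimated correlation). The counts were 4 higher and 5 lower, 679 at an unadjusted p under 0.05, against 2 and 5 without scaling, 30 and 13 in DESeq2 and 63 and 27 in the group-only fit, 26 higher with trimmed coding sequences and 16 and 8 with every counted gene tested. Leaving out 1 of the 8 libraries gave 1 to 14 higher, the most without fragmented YPD replicate 1, and 0 to 7 lower.

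Monosomes against polysomes compared 2 libraries with 1. NOP10, a small nucleolar protein gene, had no count in monosomes and 192 in polysomes, at least 7.67-fold lower, and was called in 1 of 2 fits without 1 library; it was named after its value was seen. No gene was called higher by edgeR, at 627 unadjusted p under 0.05, and DESeq2 called 10 higher and 2 lower the group-only fit 3 and 7, and a fit of every counted gene 1 and 6. The median of all genes lay at -0.52 and moved by 0.23 without scaling, with 3 higher and 1 lower, and by 0.25 in DESeq2. Cytosolic ribosomal proteins had none of 134 called, 20 lower adjusted over the list alone (camera adjusted p = 1.96e-14, and adjusted p = 0.885 with an estimated correlation). Density at -17 from the stop codon was 0 in both monosome libraries, over 4 to 10 genes, and 1.595 in the polysome library, over 1404 genes, and no fold is given. Without monosome replicate 1 the counts were 1 higher and 2 lower.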

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

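Of the tests in this part, those of sequence bias, of untreated RNY1 deletion libraries, of swapped labels and of untreated H2O2 libraries, and the whole difference with CHX on ice, were chosen only after the result was seen. Apart from the chromosome XI shift, the results here are differences between the effects of H2O2 in different groups, each by an interaction test in edgeR, limma or camera.

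In the XRN1 deletion, genes on chromosome XI lay 1.13 higher (log2) than those of the other chromosomes. All 10 equal groups of neighbouring genes along the chromosome were shifted, from 0.636 to 1.44, which an extra copy would require, so an extra copy of the chromosome may explain it. A few strongly changed genes alone would not place 86.3% of 306 genes above the median of the others. A shift of the YPD libraries would vanish against the other 5PSeq groups, where it was 0.988. No biological explanation was tested.

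The codons called higher with H2O2 in wild type, GAC, GAT, TCC and TCT, rose on average by 0.872 (AGC, TCA, TCG and AGT were not called, though AGT in H2O2 exceeded fragmented RNA by 0.76, adjusted p = 0.0144), and the rise in the RNY1 deletion was smaller for GAT (-1.04), GAC (-0.84) and TCC (-0.72), while AGA (0.25), ATC (0.25) and TTG (0.30) differed upward, these and TCC losing their call when any of the 8 libraries was left out. A fragmented mean change of 0.0569 (SE 0.0615) cannot exclude sequence bias in unfragmented libraries only. Highly counted genes alone are argued against by a mean of 0.985 without the 50 most counted, the lower library pair at 0.848. RNY1 deletion libraries that were never treated would leave SRX1 unchanged, and its adjusted p = 3.58e-04 (log2 change 5.70), though in wild type it held 2 counts with H2O2 and 1 in YPD. LYS2 (300 counts in the deletion, 300 in YPD) and MET17 (none and 1) argue against the BY4742 background on the labels, but the deposit batch differs and cannot be told apart from genotype, and in wild type with CHX on ice GAT changed by -0.01 and GAC by 0.36 (adjusted p = 0.00198).

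Oxidative stress genes rose at 5 min with CHX on ice beyond their change without CHX by a median of 1.17. Too few counts would leave a large rise possible without CHX, but for the 19 genes called with CHX the summed counts, 5911 against 4764, gave a ratio of 1.13 (1.08 to 1.17) against 3.93 (3.73 to 4.15) with CHX. Swapped H2O2 and YPD labels would make them fall, and their median change was 0.0743 (quartiles -0.318 and 0.305). The 8 codon changes, 4 of them rises kept in each fit without 1 library, cannot show exposure, as codons also changed without H2O2. SRX1 held 2 counts with H2O2 and 1 in YPD, against 165 and 6 with CHX on ice, so weak or no exposure stays open. The extra 5 min on ice after H2O2 may let mRNA or decay ends build up, a hypothesis not tested beyond these values, and read type differs between the sets.

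The change of 5PSeq ends beyond fragmented RNA passed for 4 genes upward and 5 downward (63 and 27 in a fit of only the groups compared). RPS28B (3.05), ACB1 (2.15), RPL43B (2.02) and RPL25 (1.59) were higher, and NUM1 (-2.08), EAF1 (-2.10), ZDS1 (-2.20), PIB2 (-2.45) and RSC30 (-7.89, a fitted value that is no bound) lower, those outside the naming rule being chosen after their values were seen. The codons GAT (1.06), GAC (0.85) and TCC (0.71, in 1 of 8 fits without 1 library) were higher and CGA (-1.54, lost without 4 of the 8 libraries) lower. List medians were 0.80 for cytosolic ribosomal proteins, 1.00 for histones, 0.51 for mitochondrial ribosomal proteins, 0.36 for oxidative stress defence and 0.69 for respiration, of which only histones hold with an estimated correlation.

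The H2O2 change in the RNY1 deletion beyond wild type had list medians of -0.20 for amino acid biosynthesis, -0.27 for cytosolic ribosomal proteins, -0.25 for glycolysis, -0.20 for heat shock genes, -0.26 for histones, -0.32 for mitochondrial ribosomal proteins, -0.26 for respiration and 0.31 for ribosome biogenesis. None of these 8 lists passed camera with an estimated correlation, at adjusted p from 0.596 to 0.617.

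With CHX on ice, 32 genes were higher and 11 lower beyond the change without CHX (53 and 48 in a fit of only the groups compared). FRE1 (3.27), GPX2 (3.10) and CCP1 (3.05) were higher and RPS28B (-2.65), LSO2 (-1.83, in 1 of 8 fits without 1 library) and HHF2 (-1.57, in none of 8) lower. The codons GAT (-1.08) and GAC (-0.54) were lower and density at -17 from the stop codon higher (1.73, in 3 of 8 such fits). List medians were -0.25 for cytosolic ribosomal proteins, 0.31 for heat shock genes, -0.59 for histones and -0.42 for mitochondrial ribosomal proteins, none of which passed camera with an estimated correlation.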

How the results depend on the processing

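In all, 497 results were computed under 4916 alternative values, of which 3851 kept their direction and their side of the threshold (counts within a factor of 1.5, single values within the spread between replicates), 632 stayed in direction but no longer passed, 7 newly passed, 344 moved and 82 reversed. The tests without the monosome and polysome libraries, those leaving out libraries for gene lists and S. pombe, and all those of the CHX difference were chosen after the data were seen. The frame 1 share of 5PSeq over fragmented libraries kept its direction and its test in all 50 alternatives. Named genes, mostly picked as large called changes and so likely stable, kept their calls in 1445 of 1517 alternatives, and none reversed. Gene counts moved in 51 (higher) and 65 (lower) of 197. Depth limits the monosome libraries most. DESeq2 gave no adjusted p for 10408 gene-by-comparison values, which were left out. Below, each value is followed by the reported one in parentheses, and the cause was not tested except where stated. Comparisons are named by treatment: iced 5 min and iced 30 min are H2O2 with CHX added on ice, and depleted CHX is CHX in ribosomal-RNA-depleted libraries. 5P beyond fragmented is the H2O2 change of 5PSeq beyond the fragmented change. The rny1 and CHX differences are changes of the H2O2 response with the rny1 deletion and with CHX on ice.

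A fit of only the groups compared rests on fewer libraries for its spread. H2O2 had 45 higher genes (4) and 12 lower (1), 3-AT 167 lower (59), CHX 133 higher (36) and 28 lower (5), SD 35 higher (296) and 11 lower (293) and H2O2 in rny1 7 higher (1). Iced 5 min had 165 higher genes (59) and 85 lower (6), depleted CHX 21 higher (457) and 0 lower (390), monosomes 3 higher (0) and 7 lower (1), 5P beyond fragmented 63 higher (4) and 27 lower (5) and the rny1 difference 8 higher (0) and 13 lower (0). The CHX difference had 53 higher genes (32) and 48 lower (11). Without scaling beyond library totals, counts moved in 6 comparisons. H2O2 had 2 lower genes (1), 3-AT 89 lower (59), iced 5 min 15 lower (6), depleted CHX 170 lower (390) and monosomes 3 higher (0). 5P beyond fragmented had 2 higher genes (4). DESeq2 moved counts in 8 comparisons. H2O2 had 2 lower genes (1), CHX 9 lower (5), H2O2 in rny1 0 higher (1), iced 5 min 11 lower (6) and monosomes 10 higher (0) and 2 lower (1). Fragmented H2O2 had 43 higher genes (0) and 15 lower (0), 5P beyond fragmented 30 higher (4) and 13 lower (5) and the rny1 difference 1 lower (0). Leaving out the first and last 50 nt of each coding sequence moved 4 comparisons. CHX had 12 higher genes (36) and 3 lower (5), iced 5 min 3 lower (6), monosomes 2 lower (1) and 5P beyond fragmented 26 higher (4). Testing every gene with a count moved 4 comparisons. CHX had 9 lower genes (5), H2O2 in rny1 2 higher (1), monosomes 1 higher (0) and 6 lower (1) and 5P beyond fragmented 16 higher (4) and 8 lower (5).

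With an estimated in place of a preset correlation, fewer lists passed. H2O2 had 0 higher lists (5) and 0 lower (1), the xrn1 deletion 0 higher (3) and 0 lower (2), stationary phase 1 lower (6), 3-AT 0 lower (3) and CHX 0 higher (4) and 0 lower (1). SD had 3 higher lists (8) and 0 lower (3), the rny1 deletion 0 higher (2) and 0 lower (6), H2O2 in rny1 0 higher (2) and 0 lower (1), iced 5 min 2 higher (5) and 0 lower (2) and iced 30 min 2 lower (4). Depleted CHX had 2 higher lists (4) and 0 lower (1), monosomes 0 higher (1) and 0 lower (2), fragmented H2O2 0 higher (1) and 1 lower (4), 5P beyond fragmented 1 higher (5) and the rny1 difference 0 higher (1) and 0 lower (7). The CHX difference had 1 higher list (2) and 0 lower (3). Single lists turned direction with 1 library left out on 2 occasions. Translation factors in SD, at adjusted p = 0.0404, ranged from 6.60e-04 to 0.740 and turned without SD 2. Ribosome biogenesis in depleted CHX, at adjusted p = 0.00449, ranged from 1.73e-07 to 0.578 and turned without depleted YPD 1.

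Single positions are named by their distance from the start or stop codon, with log2 changes; none of the values that turned sign passed the threshold before or after. In a fit of only the groups compared values stayed and their spread changed. Start -14 passed at 0.72 (0.72) for stationary phase and 0.58 (0.58) for the rny1 deletion. Stop -47 passed at 0.85 (0.85) for stationary phase and stop -17 at -0.54 (-0.54) for the rny1 deletion. Stop -47 at -2.73 (-2.73) for monosomes, and start -14 at 1.00 (1.00) and stop -17 at -0.78 (-0.78) for fragmented H2O2, no longer passed. Next, genes with at least 200 ends were used. Start -14 turned to 0.075 (-0.073) for H2O2, 0.15 (-0.045) for H2O2 in rny1 and 0.65 (-0.16) for iced 30 min. Stop -17 turned to 0.57 (-0.26) for 3-AT, -0.037 (0.053) for H2O2 in rny1 and 1.36 (-0.079) for iced 30 min. Stop -17 no longer passed at 1.12 (1.38) for iced 5 min, -1.17 (-0.78) for fragmented H2O2, 1.59 (1.73) for the CHX difference and 1.18 (1.48) for 5PSeq over fragmented YPD. Stop -47 turned to -0.043 (0.079) for depleted CHX and 0.81 (-0.0059) for the CHX difference. Start -14 no longer passed at 0.78 (1.00) for fragmented H2O2 and -0.33 (-0.92) for 5PSeq over fragmented H2O2. Ends were then summed over genes. Start -14 passed at 1.26 (0.72) for stationary phase and 1.12 (1.15) for 3-AT. Stop -17 turned to 0.042 (-0.26) for 3-AT and 0.28 (-0.079) for iced 30 min. Stop -47 turned to 0.22 (-0.10) for SD, 0.030 (-0.16) for the rny1 deletion, -0.0049 (0.079) for depleted CHX, 0.25 (-0.0059) for the CHX difference and 0.0079 (-0.49) for 5PSeq over fragmented YPD. Start -14 turned to 0.073 (-0.045) for H2O2 in rny1 and 0.15 (-0.16) for iced 30 min. Stop -47 no longer passed at -1.92 (-2.73) for monosomes. Start -14 no longer passed at 0.80 (1.00) for fragmented H2O2 and -0.40 (-0.92) for 5PSeq over fragmented H2O2. Stop -17 no longer passed at -0.52 (-0.78) for fragmented H2O2. Without the monosome and polysome libraries only start -14 for 3-AT newly passed, at 1.15 (1.15).

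Codon counts moved in a fit of only the groups compared. H2O2 had 0 lower codons (4), the xrn1 deletion 1 higher (0), stationary phase 0 higher (3), 3-AT 1 higher (3) and 0 lower (2) and CHX 1 higher (0) and 1 lower (0). SD had 0 higher codons (6) and 0 lower (5), H2O2 in rny1 4 lower (2), iced 5 min 0 lower (1), depleted CHX 3 higher (0) and 2 lower (1) and 5P beyond fragmented 0 lower (1). The rny1 difference had 9 higher codons (3) and 6 lower (3), the CHX difference 1 higher (0) and 5PSeq over fragmented H2O2 0 higher (5) and 0 lower (9). With an offset of 14 nt (P site) for 17 nt (A site), counts moved in most comparisons. H2O2 had 1 higher codon (4) and 0 lower (4), stationary phase 5 higher (3) and 13 lower (8), 3-AT 0 higher (3) and 0 lower (2), CHX 7 higher (0) and 4 lower (0) and SD 2 higher (6) and 3 lower (5). H2O2 in rny1 had 0 lower codons (2), iced 5 min 0 higher (1), iced 30 min 1 higher (0), depleted CHX 0 lower (1) and fragmented H2O2 2 lower (0). 5P beyond fragmented had 0 higher codons (3) and 0 lower (1), the rny1 difference 0 higher (3) and 0 lower (3), the CHX difference 1 lower (2), 5PSeq over fragmented YPD 1 higher (0) and 1 lower (0) and 5PSeq over fragmented H2O2 0 higher (5) and 0 lower (9). For H2O2, AGA 0.081 (-0.20), ATC 0.037 (-0.22), GAC -0.056 (0.90), GAT -0.087 (1.07), TCC -0.087 (0.76), TCT -0.056 (0.76) and TTG 0.084 (-0.24) turned. For 3-AT, AAA 0.073 (-0.57), ATC 0.28 (-0.30) and CTG -0.63 (0.84) turned. For SD, AGG 0.68 (-1.27), CCG -0.99 (1.30), TCA -0.082 (0.43) and TCT -0.034 (0.50) turned. For the rny1 deletion, CCA -0.29 (0.31), CCC -0.32 (0.47), CCG -0.76 (1.12) and TGT 0.029 (-0.31) turned. CCC 0.021 (-0.77) for H2O2 in rny1, CGA 1.00 (-1.05) for iced 5 min and CAC 0.30 (-0.43) for depleted CHX turned. For 5P beyond fragmented, GAC -0.10 (0.85), GAT -0.074 (1.06) and TCC -0.16 (0.71) turned. For the rny1 difference, AGA -0.056 (0.25), GAC 0.060 (-0.84), GAT 0.13 (-1.04), TCC 0.048 (-0.72) and TTG -0.10 (0.30) turned. For the CHX difference, GAC 0.082 (-0.54) turned. For 5PSeq over fragmented H2O2, ACG 0.051 (-1.15), AGT -0.22 (0.76), ATC 0.050 (-0.26), GAC -0.067 (0.89), GAT -0.034 (0.96), TCC -0.22 (0.53), TCT -0.22 (0.53) and TTG 0.081 (-0.32) turned. A minimum of 2 ends per codon leaves fewer genes. H2O2 had 0 lower codons (4), stationary phase 0 higher (3) and 1 lower (8), 3-AT 6 higher (3) and 9 lower (2), SD 0 higher (6) and 1 lower (5) and the rny1 deletion 0 higher (6) and 2 lower (19). H2O2 in rny1 had 0 lower codons (2), iced 5 min 0 higher (1) and 0 lower (1), iced 30 min 9 higher (0) and 5 lower (0), depleted CHX 0 lower (1) and fragmented H2O2 2 higher (0). The rny1 difference had 0 higher codons (3) and 1 lower (3), the CHX difference 1 lower (2) and 5PSeq over fragmented H2O2 2 higher (5) and 2 lower (9). AAA 1.00 (-0.57) for 3-AT, GGG -0.42 (1.27) for SD and CCC -0.060 (0.47) for the rny1 deletion turned. For 5PSeq over fragmented H2O2, GAG 0.057 (-0.44) turned. A denominator from the 10 codons on either side moved counts as well. Stationary phase had 0 higher codons (3) and 0 lower (8), 3-AT 4 lower (2), the rny1 deletion 7 lower (19), H2O2 in rny1 1 lower (2) and iced 5 min 3 higher (1). Iced 30 min had 1 higher codon (0), 5P beyond fragmented 0 lower (1) and the CHX difference 1 higher (0). No cap on single sites had this effect. Stationary phase had 7 higher codons (3), SD 3 lower (5), iced 5 min 3 higher (1), iced 30 min 1 higher (0) and 5PSeq over fragmented YPD 1 higher (0).

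The difference in frame 1 share, in percentage points, moved beyond the replicate spread as follows. With genes of at least 200 ends it was -4.07 (-6.15) for the xrn1 deletion, 8.56 (6.57) for stationary phase, 7.37 (9.09) for CHX and 5.87 (4.82) for the rny1 deletion. In addition it was -3.93 (-2.62) for iced 5 min, 5.70 (7.66) for 5PSeq over fragmented YPD and 7.96 (10.0) for 5PSeq over fragmented H2O2. With genes weighted equally it was -7.57 (-6.15) for the xrn1 deletion, 10.5 (9.09) for CHX, -2.05 (-2.62) for iced 5 min, 10.8 (8.60) for depleted CHX, 8.99 (7.66) for 5PSeq over fragmented YPD and 11.8 (10.0) for 5PSeq over fragmented H2O2. The S. pombe share, in percent, was 35.2 (35.3) for pooled 5PSeq reads with at least 200 ends. With genes weighted equally it was 53.9 (52.5) for 30 min CHX and 33.6 (33.1) for its fragmented libraries. Pooled fragmented reads then gave 32.2 (32.4) and pooled 5PSeq reads 35.5 (35.3). Positions capped at 20 ends gave 52.0 (52.5) for 30 min CHX and 33.3 (33.1) for its fragmented libraries. No cap gave 53.1 (52.5) for 30 min CHX. The monosome libraries had no gene with 200 ends, so that setting gave no value for them.

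With replicate number as a replicate block, H2O2 in rny1 had 1 lower codon (2), iced 30 min 1 higher (0), depleted CHX 0 lower (1), fragmented H2O2 1 lower (0) and the rny1 difference 0 higher (3). The labels do not pair the libraries, and the correlation of changes between libraries of the same number ran from -0.0449 for stationary phase to 0.225 for SD over 2603 genes.

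Each library was left out in turn; ranges run over all omissions, and the libraries after the earlier value are those whose omission moved it. A lone library left in a group is taken to vary as the other groups do. H2O2 had 1 to 2 higher (4, by all 4) and 0 lower (1, by all 4), CHX 9 to 14 higher (36, by all 4) and 0 to 1 lower (5, by all 4) and SD 80 to 333 higher (296, by SD 2, YPD 1 and 2) and 83 to 366 lower (293, by SD 2, YPD 1 and 2). The rny1 deletion had 472 to 592 lower (834, by rny1 1 and 2), H2O2 in rny1 0 to 1 higher (1, by rny1 1) and iced 5 min 35 to 48 higher (59, by iced 0 min 1 and 2) and 1 to 4 lower (6, by iced 5 min 1 and 2, iced 0 min 2). Iced 30 min had 332 to 419 higher (569, by iced 0 min 2) and 371 to 461 lower (619, by iced 30 min 1, iced 0 min 2), depleted CHX 157 to 902 higher (457, by depleted CHX 1, depleted YPD 1 and 2) and 13 to 926 lower (390, by all 4) and monosomes 0 to 1 higher (0, by monosome 1) and 1 to 2 lower (1, by monosome 1). Fragmented H2O2 had 0 to 13 higher (0, by fragmented YPD 1) and 0 to 1 lower (0, by fragmented YPD 1), 5P beyond fragmented 1 to 14 higher (4, by H2O2 1 and 2, fragmented H2O2 1, YPD 1, fragmented YPD 1 and 2) and 0 to 7 lower (5, by H2O2 1 and 2, fragmented H2O2 1 and 2, YPD 1, fragmented YPD 2) and the CHX difference 15 to 28 higher (32, by iced 0 min 1 and 2, H2O2 1, YPD 2) and 1 to 7 lower (11, by all 8).

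List counts then moved as follows. H2O2 had 3 to 6 higher (5, by H2O2 2, YPD 2), CHX 0 to 1 lower (1, by YPD 1) and SD 1 to 3 lower (3, by SD 2). H2O2 in rny1 had 0 to 2 higher (2, by rny1 1 and 2, rny1 H2O2 1) and 0 to 1 lower (1, by rny1 H2O2 1), iced 5 min 1 to 3 lower (2, by iced 5 min 1) and depleted CHX 0 to 1 lower (1, by depleted CHX 2). Monosomes had 0 higher (1, by both), fragmented H2O2 0 to 2 higher (1, by fragmented H2O2 1 and 2) and 5P beyond fragmented 3 to 5 higher (5, by fragmented YPD 2) and 1 lower (0, by all 8). The rny1 difference had 3 to 7 lower (7, by H2O2 2, rny1 1, rny1 H2O2 2, YPD 2), the CHX difference 2 to 5 higher (2, by iced 5 min 2, iced 0 min 2, H2O2 1, YPD 2).

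Codon counts then moved as follows. H2O2 had 0 to 4 lower (4, by H2O2 2, YPD 1 and 2), stationary phase 0 to 1 higher (3, by all 4) and 0 to 7 lower (8, by stationary 1, YPD 1 and 2) and 3-AT 4 to 5 higher (3, by SD-His 1) and 6 to 9 lower (2, by both). CHX had 0 to 1 higher (0, by YPD 2), SD 1 to 10 higher (6, by SD 2, YPD 1 and 2) and 2 to 7 lower (5, by SD 1, YPD 1 and 2) and the rny1 deletion 2 to 5 higher (6, by rny1 1 and 2, YPD 1) and 8 to 13 lower (19, by rny1 2, YPD 1). H2O2 in rny1 had 0 lower (2, by all 4), iced 5 min 0 to 1 higher (1, by iced 0 min 1) and 0 to 1 lower (1, by iced 0 min 1 and 2) and iced 30 min 0 to 2 higher (0, by iced 30 min 2, iced 0 min 1 and 2) and 0 to 1 lower (0, by iced 30 min 1). Depleted CHX had 0 lower (1, by all 4), fragmented H2O2 0 to 2 higher (0, by fragmented H2O2 2) and 0 to 3 lower (0, by fragmented H2O2 1 and 2) and 5P beyond fragmented 2 to 5 higher (3, by fragmented H2O2 1) and 0 to 3 lower (1, by H2O2 1 and 2, fragmented H2O2 1 and 2, YPD 1, fragmented YPD 2). The rny1 difference had 0 higher (3, by all 8), 5PSeq over fragmented YPD 0 to 1 higher (0, by fragmented YPD 2) and 0 to 1 lower (0, by YPD 2, fragmented YPD 2) and 5PSeq over fragmented H2O2 2 to 7 higher (5, by H2O2 1 and 2) and 4 to 9 lower (9, by H2O2 1 and 2).

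Among single positions, the following moved. Start -14 ran from -0.21 to 0.060 for H2O2 (-0.073, by H2O2 1), -0.33 to 0.42 for SD (0.041, by SD 1) and -0.14 to 0.050 for H2O2 in rny1 (-0.045, by rny1 2). Start -14 covered -0.80 to 0.080 for monosomes (-0.36, by monosome 1), 0.47 to 1.53 for fragmented H2O2 (1.00, by fragmented H2O2 1 and 2, fragmented YPD 2) and -0.11 to 0.16 for the rny1 difference (0.027, by H2O2 1, rny1 1, rny1 H2O2 2). Start -14 spanned -0.38 to 0.68 for 5PSeq over fragmented YPD (0.15, by fragmented YPD 2) and -1.06 to -0.79 for 5PSeq over fragmented H2O2 (-0.92, by H2O2 1, fragmented H2O2 1 and 2). Stop -47 ran from -0.48 to 0.28 for SD (-0.10, by SD 1, YPD 2), -0.19 to 0.20 for iced 30 min (0.0028, by iced 30 min 1, iced 0 min 2) and -0.10 to 0.26 for depleted CHX (0.079, by depleted CHX 2, depleted YPD 1). Stop -47 covered -4.94 to -0.53 for monosomes (-2.73, by monosome 1) and -0.20 to 0.19 for the CHX difference (-0.0059, by iced 5 min 1, iced 0 min 1, H2O2 1, YPD 1). Stop -17 ran from -0.076 to 0.18 for H2O2 in rny1 (0.053, by rny1 1), 1.24 to 1.52 for iced 5 min (1.38, by iced 5 min 2, iced 0 min 2) and -0.28 to 0.12 for iced 30 min (-0.079, by iced 30 min 1, iced 0 min 1). Stop -17 covered -0.82 to -0.75 for fragmented H2O2 (-0.78, by all 4) and 1.59 to 1.87 for the CHX difference (1.73, by iced 5 min 1 and 2, iced 0 min 2, H2O2 2, YPD 2).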

Other observations

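The results in this part were chosen after the data were seen. In stationary phase, ends 50 nt before the stop codon rose from 3.06 ± 0.561 in YPD to 7.40 ± 0.120 times the gene mean (SD, n = 2 each; log2 change 1.27, adjusted p = 0.00389). RNY1 deletion libraries of the same deposit batch held 2.73 ± 0.259 there.

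The polysome library, labelled as a strain that lacks URA3 and LEU2, held 110 counts of URA3 and 13 of LEU2, no count of HO and 5 of STE2, and the monosome libraries held 7 and 13 counts of URA3. The YPD libraries held 1 count of URA3 and none of LEU2 in sum. HO held 1473 counts in the RNY1 deletion against 315 in YPD. STE2, a marker of mating type a, held 761 counts in the RNY1 deletion, as labelled, against 797 in YPD, and STE3, a marker of type alpha, none in the deletion, 61 in stationary phase and 1 in YPD. The origin of these differences was not tested.

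In SD-His and 3-AT, from another strain, LEU2 held 127 and 316 CPM, URA3 181 and 199, and MET17 193 and 1604.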
